A study of Escherichia coli with 11 samples.

How the data were processed

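The deposited tables hold, per the file headers, whole-number counts of reads for each nucleotide of a reference rRNA: the read depth and the counts of each substitution and of each unambiguous deletion. They also hold a mutation rate as a fraction, which the authors computed. The sum of the deposited counts divided by depth gave that fraction in every table to within 4.64e-08. Per the labels' protocols, particles were separated on sucrose gradients and libraries followed the randomer workflow of a mutational profiling protocol, and a phred cutoff was applied to mutations per the file headers. The aligner, the mutation caller, their versions and further filters are not given in the sources used here. Each table held 1 library. The 23S reference has 2909 nucleotides and the 16S reference 1542, both given in the tables, and no genome was used.

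Samples were grouped by their titles. The untreated 16S table comes from the sample titled 35S replicate 2, whose description names 30S particles. A list of 25 modified nucleotides in 23S and 11 in 16S rRNA, with their chemical class, was fixed from general knowledge before the data were examined, as were the tests, the alternatives and the rule for naming nucleotides. Each listed nucleotide was placed by sequence context. The table number exceeds the E. coli number by 2 from m1G745 to m2G1835 and by 4 from Ψ1911 on, and it is the same in 16S rRNA. The base matched at all of them.

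For the 23S comparisons mutated reads per nucleotide were tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test used the log depth at that nucleotide as offset and no other scaling, 7 untreated libraries in one fit, and Benjamini-Hochberg adjustment at 0.05. Positions needed a depth of 1000 in every library and 50 mutated reads in all, which left 2730. Listed nucleotides were also adjusted over the list alone. Alternatives were TMM factors added to the offset, DESeq2 1.42.0, limma 3.58.1 on the logit of the rate with 0.5 added to both read classes, and no filter. Others were mismatches only, a replicate block, leaving out each 45S, 35S and 27S library, and only the groups compared. After the data were seen, TMM scaling and limma were also run with 27S replicate 1 left out, and the comparisons without 50S with the 50S library left out. TMM factors ran from 0.554 in 45S replicate 2 to 3.65 in 27S replicate 1.

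The test was run on simulated data with tagwise spread, 100 positions changed per fold size in 2730. For 45S against 50S, 1% of 4-fold and 17% of 16-fold changes were recovered, none of them increases. For 27S against 45S it was 2% and 47%, the latter made up of 68% of increases and 26% of decreases. Of 2530 unchanged positions at most 1 was called. The simulation gave all libraries the same background rate, so it does not test calls that come from a library-wide rise such as that in 27S replicate 1. The median fitted log2 values for 45S against 50S were 1.95 and 3.75 for true values of 2 and 4. Simulated changes at background nucleotides therefore mostly went undetected at this replication, except 16-fold increases in 27S against 45S. For KMnO4, which had 1 library per condition, no test was run. The rule for raised positions recovered 100% of 200 positions simulated with a rise of 1.5 points in each of the 4 libraries and called 0 others. All other positions were simulated at their untreated rate. This check therefore covers counting error only and does not test the rule under the rise in G background seen after KMnO4.

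Named nucleotides were chosen by 3 parts of a rule. The first took listed nucleotides whose rate in untreated 50S, or in a 30S library, exceeded the 95th percentile of unmodified nucleotides of that base, and any list member past the adjusted p. The second took, per comparison, up to 5 unlisted nucleotides each way with the largest fold among those past 0.05, with a mean rate of at least 1% in either group and no overlap between libraries. The third took the 10 largest KMnO4 rises at 6 min among positions raised at both times. Rates at single nucleotides carry Wilson intervals. Group values are means with SD over libraries. Background medians used nucleotides with a depth of at least 1000. Summaries and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.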

Results

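Ribosomal RNA modification was read out as mutations in sequenced cDNA in Escherichia coli cells that lack their own copy of the dbpA gene. DbpA is a DEAD-box RNA helicase that acts in assembly of the large ribosomal subunit. The cells carried a plasmid with either wild-type DbpA or the R331A variant, which the series title calls helicase-inactive. Ribosomal particles were separated on sucrose gradients, and rRNA was sequenced by a mutational profiling protocol in which reverse transcriptase misreads certain modified bases. The deposited tables give, for each nucleotide, the reads that cover it and the reads that carry each substitution or a deletion there. The 11 samples gave 12 tables, 9 for 23S rRNA and 3 for 16S rRNA. Untreated 23S rRNA came from 50S particles of the wild-type DbpA cells (1 library) and from 45S, 35S and 27S particles of the R331A cells (2 libraries each). RNA from 50S and 30S particles of the wild-type DbpA cells was also treated with KMnO4, an oxidant, for 3 or 6 min, followed by NaHCO3 (1 library each). The third 16S table was untreated.

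Median depth per 23S nucleotide was 41532 reads in 50S, 51624 and 37131 in 45S, 6861 and 8501 in 35S, and 12189 and 1814 in 27S. It was 10232 reads at 3 min and 13505 at 6 min of KMnO4 in 50S. In 16S rRNA it was 80188 reads in the untreated table, 16920 at 3 min and 9377.5 at 6 min. Intervals given here are Wilson 95% intervals and cover counting error only, since PCR copies were not separated. The labels do not say whether replicates came from separate cultures, so adjusted p-values can only reflect the spread between these libraries. The fit also shared its estimate of spread across nucleotides, most of them background. Very small p-values and the SEs given with folds therefore do not measure the spread between replicates at that nucleotide alone. The 50S group had 1 untreated library, and its spread was assumed to match that of the other groups. Modified nucleotides carry their E. coli numbers, and all other nucleotides are numbered as in the deposited tables.

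The first comparison asked which 23S nucleotides differed in mutation rate between the 45S particles of the R331A cells and the 50S subunits. The mutation rate at m3Ψ1915 was far lower in 45S. This base is pseudouridylated by RluD and then methylated by RlmH, which acts late, on the assembled ribosome. Its rate was 77.7% in 50S (interval 77.4 to 78.1%) and 9.19% ± 4.14 (SD, n = 2) in 45S. The fitted log2 fold change was -3.08 (SE 0.20), 8.46-fold lower, with an edgeR quasi-likelihood adjusted p of 6.06e-50. Leaving out 45S replicate 1 gave a log2 fold of -2.68 and leaving out replicate 2 gave -3.63, a wider range than that SE implies. The other call was C1660, which is not on the list of modified nucleotides. Its rate was 12.5% in 50S and 0.505% ± 0.228 (SD, n = 2) in 45S, 24.8-fold lower (log2 -4.63, SE 0.92, edgeR adjusted p = 0.000665). Of 2730 positions tested, 2 were lower and 0 were higher. Of the 25 listed nucleotides, 1 was lower, both over all positions and adjusted over the list alone.

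The other bases that are read as mutations did not pass the test between 45S and 50S. At m1G745, made by RlmA, rates were 73.2% in 50S and 76.4% ± 2.18 (SD, n = 2) in 45S. At m2G1835, made by RlmG, they were 62.7% and 56.5% ± 12.6 (SD, n = 2), and at m2G2445, made by RlmKL, 4.37% and 5.14% ± 0.743 (SD, n = 2). At m2A2503, made by RlmN, they were 0.449% and 0.192% ± 0.0882 (SD, n = 2). Of the 6 listed bases methylated on the Watson-Crick face, 1 was lower and 5 did not pass. None of the 9 pseudouridines, 3 ribose methylations, 5 base methylations off that face or 2 other base modifications passed. In untreated 50S only m1G745, m2G1835, m3Ψ1915, m2G2445 and m2A2503 lay above the 95th percentile of unmodified nucleotides of their base. The other listed modifications were not read above background there, so a loss of them could hardly show as a lower rate. With TMM scaling of the background the m3Ψ1915 log2 fold was -2.91 (SE 1.12, edgeR adjusted p = 1.00), and with DESeq2 it was -2.89 (SE 0.94, adjusted p = 0.639). C1660 did not pass with TMM scaling or limma, nor without 45S replicate 1, but its log2 fold stayed between -5.19 and -4.23 in every setting. All of these rest on the untreated 50S library. After KMnO4 the C1660 rate in 50S was 5.87% and 6.25%, so the size of the fold depends on which 50S library is used.

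**Figure D1:**
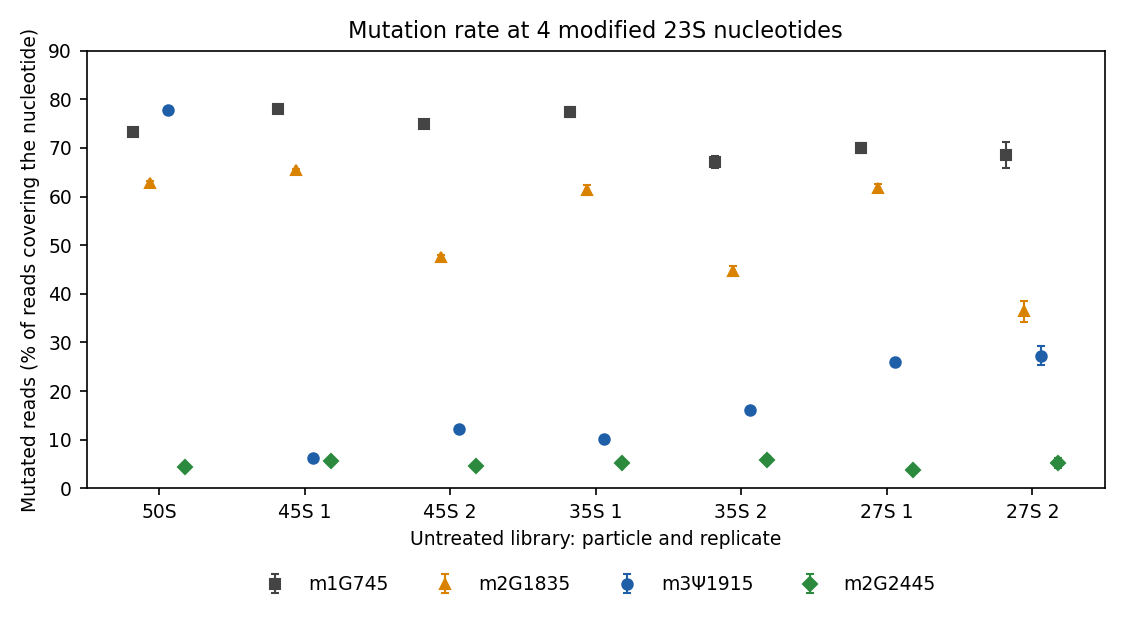
Mutation rate (percent of covering reads, y axis) at 4 modified 23S nucleotides in each of the 7 untreated libraries (x axis); bars are Wilson 95% intervals. The m3Ψ1915 rate is 77.7% in 50S and between 6.26% and 27.3% in the R331A libraries, while m1G745 lies between 67.2% and 78.0% in all 7.

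The second comparison set 35S particles against 50S. The same pair of nucleotides was called as for 45S, against the same single 50S library. At m3Ψ1915 the rate was 13.1% ± 4.16 (SD, n = 2) in 35S, 5.91-fold lower than in 50S (log2 -2.56, SE 0.20, edgeR adjusted p = 9.75e-35). At C1660 it was 0.286% ± 0.105 (SD, n = 2), 43.7-fold lower (log2 -5.45, SE 0.95, edgeR adjusted p = 1.50e-05). At m1G745 the 35S rate was 72.3% ± 7.25 (SD, n = 2) and at m2G2445 5.51% ± 0.443 (SD, n = 2), and neither passed. Of the 25 listed nucleotides 1 was lower, over all positions and adjusted over the list alone. The other 24, most of them not read above background in 50S, did not pass. With TMM scaling 0 positions were called, and m3Ψ1915 had a log2 fold of -3.04 and an adjusted p of 0.999. DESeq2, which gave no adjusted p at 2329 of the 2730 positions, called 12 of the others, m3Ψ1915 among them. C1660 did not pass with TMM scaling or when either 35S library was left out, but its log2 fold stayed between -5.95 and -5.12 in every setting.

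The third comparison set 27S particles against 50S. At m3Ψ1915 the rate was 26.6% ± 1.01 (SD, n = 2) in 27S, 2.92-fold lower than in 50S (log2 -1.55, SE 0.20, edgeR adjusted p = 1.33e-11). It was the 1 position of 2730 called over all positions. Adjusted over the list alone, 2 listed nucleotides were lower, m3Ψ1915 and m2G1835. At m2G1835 the 27S rate was 49.1% ± 18.0 (SD, n = 2) against 62.7% in 50S (log2 -0.35, SE 0.12, edgeR list-alone adjusted p = 0.0351, over all positions 0.165). That difference came from 27S replicate 2 (36.4%), since replicate 1 stood at 61.8%. Replicate 2 of 45S (47.5%) and of 35S (44.7%) also lay below replicate 1 (65.4% and 61.3%). At C1660 the 27S libraries gave 2.17% and 0.809%. Without 27S replicate 2, which has the lowest depth, edgeR called 1432 positions. With TMM scaling of all 7 libraries it called 0, and the m3Ψ1915 log2 fold was -2.96 (SE 1.12, adjusted p = 0.607), and with DESeq2 -2.96 (SE 0.94, adjusted p = 0.454 over all positions, 0.0415 over the list alone).

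Comparing the intermediates with each other, m3Ψ1915 mutated more often in 27S than in 45S or 35S. The rise from 45S to 27S was 2.89-fold (log2 1.53, SE 0.17, edgeR adjusted p = 1.09e-15) and from 35S to 27S 2.02-fold (log2 1.02, SE 0.17, edgeR adjusted p = 5.31e-06). Between 35S and 45S the log2 fold was 0.52 (SE 0.17, edgeR adjusted p = 0.992 over all positions, 0.0516 adjusted over the list alone). Rates were 6.26% and 12.1% in the 45S libraries, 10.2% and 16.1% in 35S, and 25.9% and 27.3% in 27S. The 35S against 45S difference passed over all positions without 45S replicate 2, 27S replicate 1 or 27S replicate 2 (edgeR adjusted p = 0.00199, 0.00322 and 0.0483). Without 35S replicate 1 the 27S against 35S fold was 0.72 on the log2 scale, with an edgeR adjusted p of 0.859 over all positions and 0.0186 adjusted over the list alone. With TMM scaling the 27S against 45S log2 fold was -0.049 (SE 0.95) and with DESeq2 -0.068 (SE 0.77), and the 27S against 35S log2 fold was 0.084 (SE 0.95) and 0.091 (SE 0.77), none of which passed. With limma the 27S against 35S fold was 1.29 (SE 0.32), which did not pass over all positions (adjusted p = 0.336) but did over the list alone (0.00766).

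Over all positions, edgeR called 770 nucleotides higher and 0 lower in 27S than in 45S, of which 299 were G, 280 A, 124 C and 67 U. Named by size among those not on the list were G1127 (4.23% ± 5.39 in 27S, SD, n = 2, against 0.0686%), G2736, G2592, G2395 and G976. Their fitted folds ran from 61.7 for G1127 to 38.4 for G976, and each had a far higher rate in 27S replicate 1. The G1127 rate was 8.04% in that library and 0.414% in replicate 2. The calls included 5 listed nucleotides, m3Ψ1915, Ψ746, m5U747, m5U1939 and Gm2251. Adjusted over the list alone 3 passed, m3Ψ1915, Ψ746 and m5U1939. At Ψ746 the 27S rates were 0.444% in replicate 1 and 0 in replicate 2, where the Wilson interval for a count of 0 reaches 0.323%. The median rate at unmodified G was 0.989% in 27S replicate 1 and 0.276% in replicate 2. Without replicate 1 edgeR called 2 positions, m3Ψ1915 (higher) and m2G1835 (lower). The count was 1 when either 45S library or either 35S library was left out, 1949 without 27S replicate 2, and 1 with DESeq2 (0 higher, 1 lower).

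In 27S against 35S edgeR called 5 positions, all higher. They were m3Ψ1915, G1127, C1106, G386 and A1498, the last outside the naming rule and added after its values were seen. Rates at C1106 were 8.00% in 27S replicate 1, 0.154% in replicate 2 and 0.104% ± 0.0210 (SD, n = 2) in 35S. Without 35S replicate 1 the count was 0, without 27S replicate 1 it was 2, and without 27S replicate 2 it was 1160. In 35S against 45S edgeR called 0 positions, with 8 at an unadjusted p under 0.05. DESeq2 and limma also called 0. In the main fit 0 of the 25 listed nucleotides passed when adjusted over the list alone, but m3Ψ1915 did with the replicate block described below.

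KMnO4 treatment of 50S RNA raised the mutation rate at 3 listed 23S nucleotides, each of which had hardly mutated without it. At ho5C2501, a hydroxycytidine made by RlhA, the rate went from 0.571% to 41.1% at 3 min (interval 40.0 to 42.3%) and 40.9% at 6 min. At m7G2069, made by RlmKL, it went from 0.179% to 14.0% and 13.8%. At D2449, a dihydrouridine made by RdsA, it went from 0.0579% to 9.33% and 9.28%. For these nucleotides the ratio of the 6 min to the 3 min rate was 0.994, 0.990 and 0.995. For the 515 unlisted nucleotides raised at both times the median ratio was 1.37, and for 7 of them it was at most 1. The unlisted G1225 went from 0.0807% to 15.6% and 22.8%, and U1525 from 0.0972% to 15.2% and 22.7%. The other nucleotides among the 10 largest rises, G676, G1273, G220, G1635 and G1227, reached 7.31% to 9.28% at 6 min. There was 1 library per time, so none of these differences has a replicate check.

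A position counted as raised if its rate was at least 2 times the untreated rate and at least 1 percentage point above it, with intervals apart. In 23S rRNA 523 of 2866 positions were raised at 3 min and 693 of 2871 at 6 min. Of the 518 raised at both times, 497 were G, which is 55.0% of the G tested. The median of unmodified G itself rose from 0.131% to 1.30% and 1.76%, by more than the minimum of 1 point. The medians of C, U and A at 6 min, 0.416%, 0.406% and 0.185%, lay below that minimum. The share of G among raised positions is therefore set in part by this minimum. The remaining 22 listed 23S nucleotides were not counted as raised. Among them m3Ψ1915, m1G745 and m2G1835 had untreated rates too high to reach 2 times that rate, so the rule could not count them. At m3Ψ1915 the rate was 75.7% at 3 min and 76.3% at 6 min against 77.7% untreated, and at m1G745 it was 69.5% and 69.4% against 73.2%. At m2G1835 it was 54.9% and 54.5% against 62.7%. Counts moved by over 1.5 times with the minimum rise, to 917 and 1106 at 0.5 points and to 142 and 305 at 2 points. With mismatches only 346 were raised at 3 min.

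**Figure D2:**
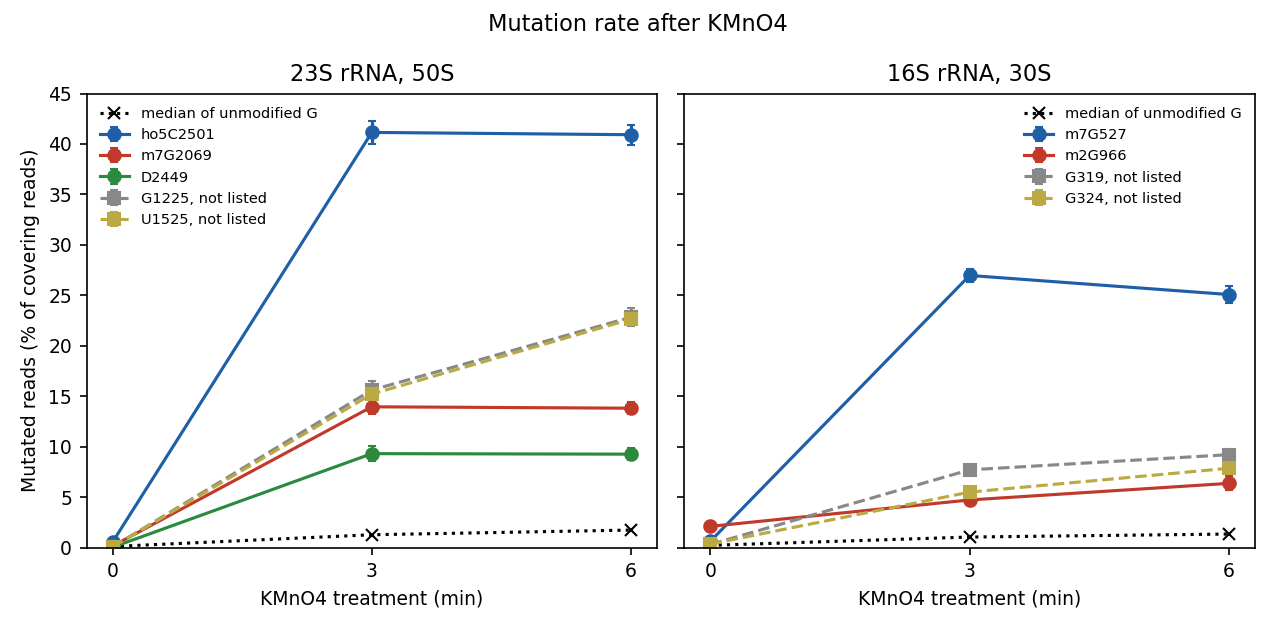
Mutation rate (percent of covering reads, y axis) against KMnO4 time in minutes (x axis) in 23S rRNA of 50S and 16S rRNA of 30S, 1 library per time, with Wilson 95% intervals. Rates at ho5C2501, m7G2069 and D2449 stay level from 3 to 6 min, while unlisted G1225 rises from 15.6% to 22.8% and the median of unmodified G from 1.30% to 1.76%.

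In 16S rRNA the same treatment raised m7G527, made by RsmG, from 0.655% to 27.0% at 3 min and 25.1% at 6 min. Of the 11 listed nucleotides, all were tested at 3 min and 8 at 6 min. At 6 min m2G1516, m62A1518 and m62A1519 had depths of only 715, 526 and 530 reads, and m2G1516, at 0.735% untreated, 1.54% at 3 min and 2.10% at 6 min, stays undecided. Another 2 listed nucleotides counted as raised at both times. They were m2G966, made by RsmD, which went from 2.13% to 4.74% and 6.38%, and m5C967, made by RsmB, from 0.241% to 1.52% and 2.06%. At m5C967 deletions made up 78.6% and 80% of mutated reads after KMnO4. Its mismatch-only rate was 0.211% untreated, 0.325% at 3 min and 0.413% at 6 min, a rise below the minimum of 1 point. Its call therefore rests on deletions. At the neighbouring m2G966 deletions also rose, from 0.165% to 1.51% and 2.48%. The unlisted nucleotides with the largest rises were G319 (0.340% to 9.23% at 6 min), G324, G266, G265, G159, G821, G778 and G727, the others of which reached 3.55% to 7.88%. Bases methylated on the Watson-Crick face mutated without treatment. The m3U1498 rate was 53.3% untreated, 54.9% at 3 min and 55.8% at 6 min. This untreated rate is too high to reach 2 times its value, so the rule could not count m3U1498 as raised. The m62A1519 rate was 20.0%, 23.4% and 23.8%, m62A1518 1.86%, 1.77% and 2.66%, and m4Cm1402 1.55%, 1.29% and 1.25%. At m2G1207 it went from 8.95% to 14.0% and 14.6%, which is 1.63 times the untreated rate at 6 min.

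In 16S rRNA 169 of 1501 positions were raised at 3 min and 269 of 1471 at 6 min, and of the 158 raised at both times 150 were G. The untreated 16S table belongs to a sample titled 35S replicate 2 of the R331A cells, while its description names 16S rRNA from 30S particles. The strain and particle of this baseline are therefore uncertain, and differences from it can include differences between cells. The rule gave 18 and 58 positions with a rise of at least 2 points, 381 and 461 with 0.5 points, and 74 and 173 with mismatches only.

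In each of the 12 tables G had the highest median mutation rate of the 4 bases at nucleotides not annotated as modified. By mean rate C was the highest in untreated 50S, 45S replicate 2, 27S replicate 2 and the untreated 16S table. The means include unlisted nucleotides with high rates, such as C264 (60.7%) and C357 (55.7%) in untreated 50S. The median rate at unmodified G was 0.131% in 50S, 0.131% and 0.101% in 45S, 0.131% and 0.258% in 35S, and 0.989% and 0.276% in 27S. For A the medians were 0.0492% in 50S, 0.0572% and 0.0427% in 45S, 0.0601% and 0.0910% in 35S, and 0.338% and 0.0943% in 27S. For C they were 0.0978%, 0.0879% and 0.0993%, 0.0983% and 0.193%, and 0.584% and 0.177% in the same order. For U they were 0.0786%, 0.0868% and 0.0580%, 0.0988% and 0.107%, and 0.308% and 0.116%. After KMnO4 the 50S medians at 3 and 6 min were 1.30% and 1.76% for G, 0.336% and 0.416% for C, 0.309% and 0.406% for U, and 0.161% and 0.185% for A. The fold over untreated 50S at 6 min was 13.5 for G, 5.17 for U, 4.26 for C and 3.76 for A. In 16S rRNA the G median went from 0.247% to 1.07% and 1.37%, C from 0.186% to 0.315% and 0.394%, U from 0.121% to 0.295% and 0.367%, and A from 0.0793% to 0.138% and 0.153%.

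**Figure D3:**
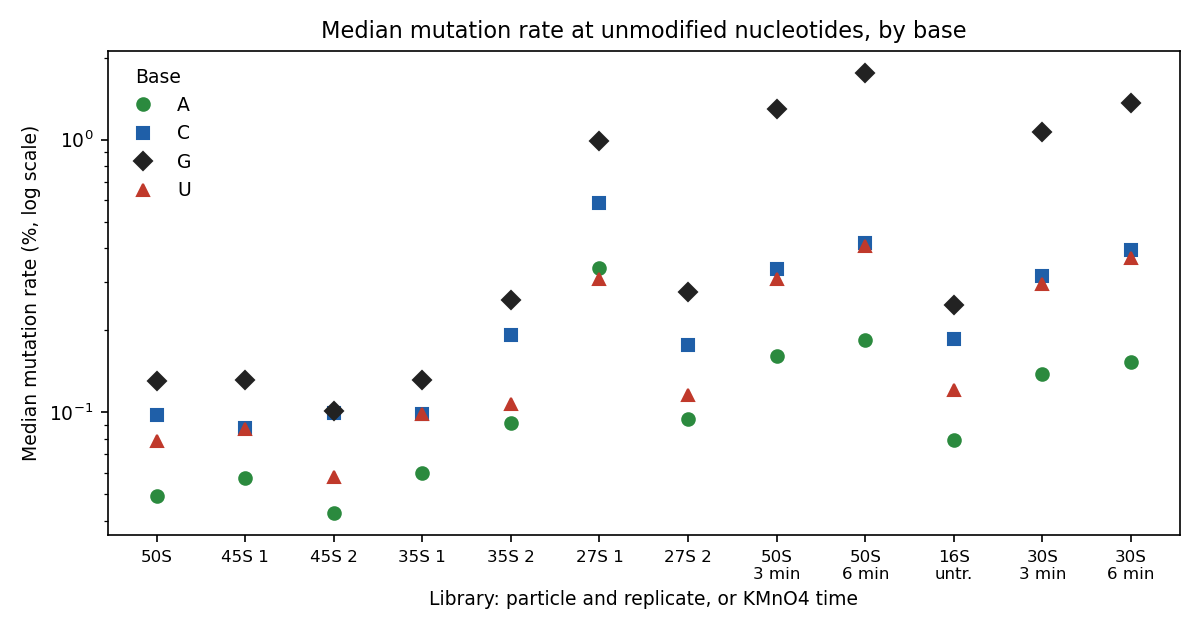
Median mutation rate (percent, log scale, y axis) at nucleotides not annotated as modified, for each base in each of the 12 tables (x axis). The G median of 27S replicate 1, 0.989%, lies near the KMnO4 libraries and above every other untreated library.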

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

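The tests in this part were chosen after the results were seen. The tables count ambiguous deletions, which their mutation rates leave out. Per 10000 covering bases, that is, read depth summed over nucleotides, they numbered 4.10 in untreated 50S and 4.74 in the untreated 16S table. They stood above that level in 50S KMnO4 at 3 min (17.2) and 6 min (23.7), in 30S KMnO4 at 3 min (15.0) and 6 min (19.8), and in the untreated 27S replicate 1 (23.3). The other R331A libraries lay below the 50S level.

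In 27S replicate 1 the rate at unmodified nucleotides was also raised, by 7.57-fold over 50S for G and 6.88-fold for A. A KMnO4-treated library under the wrong label, as the whole cause, is argued against by the bases that rose. KMnO4 raised A less than G, with a fold for A of at most 0.402 of that for G in the 4 treated libraries. From 27S replicate 2 to replicate 1 it was 0.999 of it (bootstrap 95% interval 0.879 to 1.21). Of the listed nucleotides raised by KMnO4 in 50S, m7G2069 (0.837%) and D2449 (0.231%) stayed low in 27S replicate 1, and ho5C2501 stood at 6.59%. How far 27S carries these modifications was not measured. The share of G-to-A changes, however, was close to that after KMnO4. At unmodified G with rates under 5% it was 16.0%, against 19.8% and 16.3% in treated 50S and 35.6% in 27S replicate 2. A part for KMnO4 in the rise therefore stays open. Low depth is argued against by 27S replicate 2, which is shallower and had a G median of 0.276%. The 27S particle itself stays open: the 27S replicates differed 3.59-fold in the G median, against 1.97-fold between the 35S and 1.30-fold between the 45S replicates, and 27S replicate 2 was 2.11-fold above 50S.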

How the results depend on the processing

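Read depth limits the comparisons most in 27S replicate 2, and no position reached a depth of 5000 in every library, so that minimum gave no value for the 23S comparisons. TMM scaling called 0 positions in 45S, 35S and 27S against 50S and in 27S against 45S and 35S, and 0 listed nucleotides in each. It left 0 positions in all 5 with 27S replicate 1 also left out, and 0 listed nucleotides in 27S against 50S, 45S and 35S, but 1, m3Ψ1915, in 45S and in 35S against 50S. DESeq2 called 1 position in 45S against 50S, 12 in 35S against 50S, 1 in 27S against 45S and 0 in 27S against 35S. Over the list alone it called 0 in 45S against 50S, 1 in 27S against 50S (m3Ψ1915), and 0 in 27S against 45S and 35S. On the logit scale limma called 1 position in 45S against 50S, 1 in 27S against 45S and 0 in 27S against 35S, and 1 listed nucleotide in 27S against 50S. With 27S replicate 1 left out, limma called 2, 3 and 0 positions in 27S against 50S, 45S and 35S, and 2 listed nucleotides in 27S against 35S. No filter gave 9 positions in 27S against 35S and 1 listed nucleotide in 27S against 50S. With only the groups compared, edgeR called 7 positions in 35S against 50S, and 1 each in 27S against 45S and 35S, with 1 listed nucleotide in 27S against 50S and 1 against 45S. The cause was not tested.

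The replicate block used the replicate numbers of the labels. Deviations of same-numbered libraries correlated at 0.546 between 45S and 35S, so these share something beyond their group, but at -0.0362 between 45S and 27S and -0.00756 between 35S and 27S. Log rates correlated at 0.881 (replicate 1) and 0.807 (replicate 2) between 45S and 35S, above the 0.690 between the 45S and 0.683 between the 35S replicates. The labels name no shared culture or day, so the numbers were not taken to pair the samples in the main fit. With the block, counts were 2 in 27S against 50S, 1 in 27S against 45S and 1 in 27S against 35S. Over the list alone 1 nucleotide was called in 27S against 50S and 1 in 35S against 45S, m3Ψ1915 both times. In 35S against 45S its list-alone edgeR adjusted p was 0.000772 with the block and 0.0516 without it.

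For m3Ψ1915, log2 folds against 50S with TMM scaling were -2.91 (45S), -3.04 (35S) and -2.96 (27S), and with 27S replicate 1 also left out -2.93, -3.06 and -2.36. None passed over all positions. Over the list alone those for 45S and 35S passed with 27S replicate 1 left out (adjusted p = 0.0126 and 0.00879). DESeq2 gave -2.89 (45S) and -2.96 (27S), not past the threshold over all positions, and the latter passed over the list alone (0.0415). Signs turned in 35S against 45S with TMM scaling (-0.13), DESeq2 (-0.16) and TMM scaling without 27S replicate 1 (-0.13), and in 27S against 45S with TMM scaling (-0.049) and DESeq2 (-0.068). The latter comparison gave 0.57, not past the threshold, with TMM scaling and 27S replicate 1 left out. In 27S against 35S the call over all positions was lost with TMM scaling (0.084), DESeq2 (0.091), limma (1.29), and without 27S replicate 1 under TMM scaling (0.70) and limma (1.35). Over the list alone both limma fits called it (adjusted p = 0.00766 and 0.00199), and the TMM and DESeq2 fits did not. TMM and DESeq2 factors multiply the expected rate at every nucleotide, so by construction they also move sites whose mutations do not come from the background. At m5U747 the 27S against 45S fold turned to -0.46 with TMM scaling and 27S replicate 1 left out.

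Leaving out one 45S, 35S or 27S library at a time gave 1 to 2 positions in 45S against 50S, 1 to 3 in 35S against 50S, 1 to 1432 in 27S against 50S, 0 to 1 in 35S against 45S, 1 to 1949 in 27S against 45S and 0 to 1160 in 27S against 35S. Over the list alone the ranges were 1 to 2 (35S against 50S), 1 to 9 (27S against 50S), 0 to 1 (35S against 45S), 1 to 14 (27S against 45S) and 1 to 9 (27S against 35S). The m3Ψ1915 log2 fold ran from 0.12 to 1.07 in 35S against 45S and from 0.72 to 1.38 in 27S against 35S. In the 3 comparisons with 50S it stayed past the threshold in each of these fits. Leaving out the 50S library gave 0 positions in 35S against 45S, 761 in 27S against 45S and 5 in 27S against 35S, and 0, 3 and 1 over the list alone. The call at Gm2251 in 27S against 45S was then lost at an unmoved log2 fold of 2.95 (adjusted p = 0.0508, 0.0495 in the main fit).

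For KMnO4, a minimum rise of 0.5 points gave 917 and 1106 raised 23S positions at 3 and 6 min and 381 and 461 in 16S, and 2 points gave 142 and 305, and 18 and 58. Mismatches only gave 346 at 3 min in 23S, and 74 and 173 in 16S. Means in place of medians at unmodified nucleotides are given for 50S, 45S replicates 1 and 2, 35S 1 and 2, 27S 1 and 2, 50S at 3 and 6 min, untreated 16S, and 30S at 3 and 6 min. For A they were 0.216, 0.232, 0.196, 0.226, 0.245, 0.561, 0.207, 0.324, 0.357, 0.368, 0.422 and 0.431%. For C they were 0.445, 0.388, 0.379, 0.389, 0.482, 0.934, 0.474, 0.626, 0.726, 0.709, 0.756 and 0.831%. For G they were 0.400, 0.412, 0.335, 0.394, 0.486, 1.46, 0.471, 1.62, 2.14, 0.367, 1.20 and 1.53%. For U they were 0.364, 0.392, 0.322, 0.389, 0.383, 0.596, 0.330, 0.632, 0.735, 0.659, 0.809 and 0.878%. Mismatch-only medians that moved were 0.0780 and 0.0875% for C in 45S and 0.0891 and 0.0931% for U in 35S. After KMnO4 they were 0.993 (G) and 0.203% (U) in 50S at 3 min, 0.123 (A), 0.316 (C), 1.31 (G) and 0.237% (U) at 6 min, and 0.848 and 0.204%, then 1.07 and 0.225%, for G and U in 30S at 3 and 6 min. With a minimum depth of 5000 all 44 medians that could be computed stayed within their error.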

Other observations

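The tests in this part were chosen after the results were seen. At ho5C2501 untreated rates were 0.571% in 50S, 0.947% and 1.81% in 45S, 0.314% and 2.17% in 35S, and 6.59% and 2.70% in 27S. The changes at C1660 in 50S were mixed, with 54.7% of mutated reads C1660G, 32.9% C1660T and 11.1% deletions. Mutated reads at m2G1835 were 94.9% G1837C in 50S, and at m3Ψ1915 73.8% T1919A and 24.4% T1919G, numbered as in the tables. Among unmodified G with a rate under 5%, G-to-A made up 50.5% of mutated reads in 50S and 61.7% and 65.3% in replicate 1 of 45S and 35S. It made up 16.0% in 27S replicate 1, and 35.7%, 39.7% and 35.6% in replicate 2 of 45S, 35S and 27S. After KMnO4 it made up 19.8% at 3 min and 16.3% at 6 min in 50S. In 16S rRNA, 3 nucleotides were far higher in the untreated table than after 6 min of KMnO4: C271 (14.9% against 4.39%), C856 (12.4% against 1.34%) and G867 (7.89% against 1.43%).

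The lower m3Ψ1915 rate in the R331A libraries was weighed against technical explanations. Poorer read-out of modified bases as the whole cause is argued against in 45S and 35S. There m1G745, m2G1835 and m2G2445 kept at least 0.758 and 0.713 of their 50S rates, while m3Ψ1915 had at most 0.156 and 0.207 of its own. In 27S replicate 1 they kept at least 0.866, with m3Ψ1915 at 0.333. In 27S as a group it stays open, since in replicate 2 m2G1835 stood at 0.580 and m3Ψ1915 at 0.351, although m1G745 (0.936) and m2G2445 (1.18) did not fall as far there. The lowest values in 45S and 35S were also those of m2G1835 in replicate 2. An untreated 50S library that stands out is argued against by the KMnO4-treated 50S libraries, with m3Ψ1915 rates of 75.7% and 76.3%. The labels do not say whether the 50S libraries share a culture, so spread between cultures stays open. Mature rRNA in the 27S fraction may account for its higher rate than in 45S. That would need a share of 26.4% and, going by the untreated 50S library, a C1660 rate of 3.69% in 27S replicate 2. There 0.809% was measured, and 2.17% in 27S replicate 1. The KMnO4-treated 50S libraries had C1660 rates of only 5.87% and 6.25%, which would lower the level needed. The C1660 level of mature R331A rRNA was not measured here, so this stays open. Cells and particle differ together between 50S and the rest, so the DbpA variant and the assembly stage are confounded in comparisons with 50S, and the variant was not tested alone.

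Besides C1660, 22 unlisted 23S nucleotides had a rate of at least 10% in untreated 50S, in 13 clusters of neighbours with similar rates. A83 (26.3%), U137 (26.0%), C357 (55.7%), G1725 (71.1%) and U1476 (14.7%) are examples. A candidate explanation is sequence differences between rRNA operons, of which the K-12 MG1655 gene table lists 7 with a 23S gene. Rates lay 2.19 points on average from multiples of 1 in 7, against 3.50 for random rates. Of 100000 draws of random rates for the 13 clusters, a share of 0.00966 lay as close. The draws took clusters as independent, although differences on the same operon copy would share a rate. Several clusters also lay between 12% and 18%, just above the 10% cutoff and around 1 in 7. The share may therefore overstate how unusual the closeness is. Modified nucleotides missing from the list stay open: the commonest change made up a median of 99.6% of mutated reads, above the 61.9% to 94.9% at 4 listed nucleotides, but so few do not set the range for other modifications.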
